A study of Mus musculus with 24 samples.

How the data were processed

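Nuclei of mouse kidney from a sham group and 5 groups at 4 hours, 12 hours, 2 days, 14 days and 6 weeks after IRI were studied, with 3 replicates in each. Per the labels, nuclei were isolated by Dounce homogenization in lysis buffer and filtering. The extract protocol names inDrops and 10x or Dropseq, and the design text of the series names 10X Chromium for the injured kidneys. The authors deposited raw UMI counts per gene and nucleus, 1 table for each group, with a table of cell type names. STAR 2.5.3a, mm10 and hg19 stand in the submitters' processing notes with no role given. Every value was checked to be a whole number of at least 0. The handling of doublets, cell calling and intron reads was not given in the sources used here. Gene coordinates were taken from GENCODE vM21 (GRCm38, mm10) by symbol.

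Libraries labelled such as 1_1 and 1_2 were read as of 1 replicate, which the labels do not say outright, and were summed, which made 18 replicates of 24 libraries. The labels do not say that replicates are separate animals, so p-values measure only the spread between samples. The 26 names of the authors' annotation were merged into 13 classes. Proximal tubule held every name with PT, its new states included, and thick ascending limb the cortical and medullary names without macula densa. Stroma held fibroblasts and pericytes. UMIs were summed over the nuclei of a class in each replicate, with at least 20 nuclei required, which every replicate had in the 5 classes tested for genes.

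Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust quasi-likelihood fits of all 6 groups with no covariate, and F-tests of each time against sham. Adjustment was by Benjamini-Hochberg within each contrast, with a threshold of 0.05. A joint test of the 5 times gave the genes that differ among groups. Errors of log2 changes are SE, in edgeR taken as the size of the log2 change over the square root of its F statistic. Errors of CPM and of shares are SD between replicates. For a group at 0 counts a lower bound of the fold was computed with a floor of 3 counts over the group.

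There were 26 gene lists. Lists with at least 5 tested members were tested with camera (limma 3.58.1, correlation preset at 0.01), adjusted over lists and times within each class. Members were counted over all genes tested and adjusted over the list alone. Shares were tested with edgeR on numbers of nuclei with the total of the replicate as library size, adjusted over classes and times, beside an exact permutation test. Responses of proximal tubule and thick ascending limb were compared with limma on the difference of list means of log2 CPM (prior count 2) within each replicate, for 4 lists. Variances were moderated over the 4 lists.

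The tests, classes, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took, in each class and time, the 3 largest rises and 3 largest falls in log2 change among genes past the threshold. They needed a mean of at least 20 CPM in the higher group and all replicates of a group above all of the other. Symbols starting with mt- or with Gm and a digit or ending in Rik were left out, as were genes with a mean CPM more than 5 times higher in another tested class, as possible free RNA. To these it added up to 4 measured members with the smallest p of each list described. It also added Havcr1, Lcn2 and Vcam1 in every class, Slc34a1 and Slc5a12 in proximal tubule, Umod and Slc12a1 in thick ascending limb, Slc12a3 and Calb1 in distal convoluted and connecting tubule, Flt1 and Emcn in endothelium, and Pdgfrb and Col1a1 in stroma. The lists and shares described, and the part of the genes given by the rule that the text names, were picked after values were seen. In that pick, genes whose call was lost on leaving out a single replicate were mostly passed over. Many genes that the rule gives are not named, and 1 is not reported here for a reason apart from its values.

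Alternatives were relative log expression factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each replicate, only the groups compared, and the first library of each replicate. Others were the same number of nuclei drawn from every replicate (seed 1), and leaving out possible free RNA genes. Lists were also tested with an estimated correlation and with fry, and responses with a prior count of 0.5. Shares were also tested with TMM over classes, with nuclei of at least the median UMIs, and without proximal tubule nuclei in the total. After the data were seen, fits of the large libraries alone (boundary 4000 nuclei) and with library size class as a term were added. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

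The precision of the gene test was tested on simulated data with the depth and spread of each class, 2 days against sham, with 200 genes changed. At 4-fold the test recovered 38% in proximal tubule, 37% in thick ascending limb, 24% in distal convoluted and connecting tubule, 55% in endothelium and 51% in stroma. At 2-fold it recovered 4%, 3%, 3%, 1% and 7%. False calls were 1 of 43, 2 of 42, 0 of 27, 6 of 62 and 9 of 67, in the same order.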

Results

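Single nuclei of mouse kidney were profiled in a time course of acute kidney injury. The nuclei came from a sham group and from 5 groups named IRI at 4 hours, 12 hours, 2 days, 14 days and 6 weeks. IRI is a usual short form of ischaemia-reperfusion injury in kidney research, the loss and return of blood flow to the organ. Each group held 3 replicates, deposited as 4, 3, 4, 5, 4 and 4 libraries in the order sham to 6 weeks, and libraries read from their labels as of the same replicate were summed. The tables held 126578 nuclei, 27133 genes and 198008986 unique molecular identifiers (UMIs), each a count of 1 captured RNA molecule. Total UMIs of replicates 1, 2 and 3 were 24136970, 6745836 and 6478705 in sham and 10410789, 3541188 and 7329138 at 4 hours. They were 16605319, 7055686 and 7092445 at 12 hours, and 27161140, 11702943 and 5361311 at 2 days. At 14 days they were 24215930, 4182083 and 3528126, and at 6 weeks 22690595, 3345759 and 6425023. Median UMIs per nucleus ran from 1123 in replicate 3 at 6 weeks to 2495.5 in replicate 3 at 2 days.

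Libraries fell into a small and a large set. There were 7 libraries with 1944 to 2315 nuclei, and the others held 4529 to 8513. The small libraries made up replicate 2 at 4 hours, replicates 2 and 3 at 2 days, replicates 2 and 3 at 14 days and replicate 2 at 6 weeks, and no sham replicate. All 3 replicates at 12 hours came from large libraries. At 2 and at 14 days the large set left 1 injured replicate, whose spread was then taken from the other groups.

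The authors' annotation of 26 cell types was grouped into 13 classes. Genes were tested in 5 classes set before the data were examined: proximal tubule, which reclaims most of the filtered load, thick ascending limb, distal convoluted and connecting tubule, endothelium and stroma. Replicate totals ran from 1483252 to 17796598 UMIs in proximal tubule, 516214 to 4662607 in thick ascending limb and 313026 to 2932542 in distal convoluted and connecting tubule. Endothelium held 97402 to 1133598 and stroma 62851 to 541718. For each class the question was which genes differed from sham at each time. Across the 6 groups 4976 of 15644 tested genes differed in proximal tubule, 2308 of 13152 in thick ascending limb and 1658 of 11194 in distal convoluted and connecting tubule. In endothelium 1484 of 10154 differed, and in stroma 1552 of 6741. Without replicate 1 at 2 days the thick ascending limb count was 3491.

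**Figure D1:**
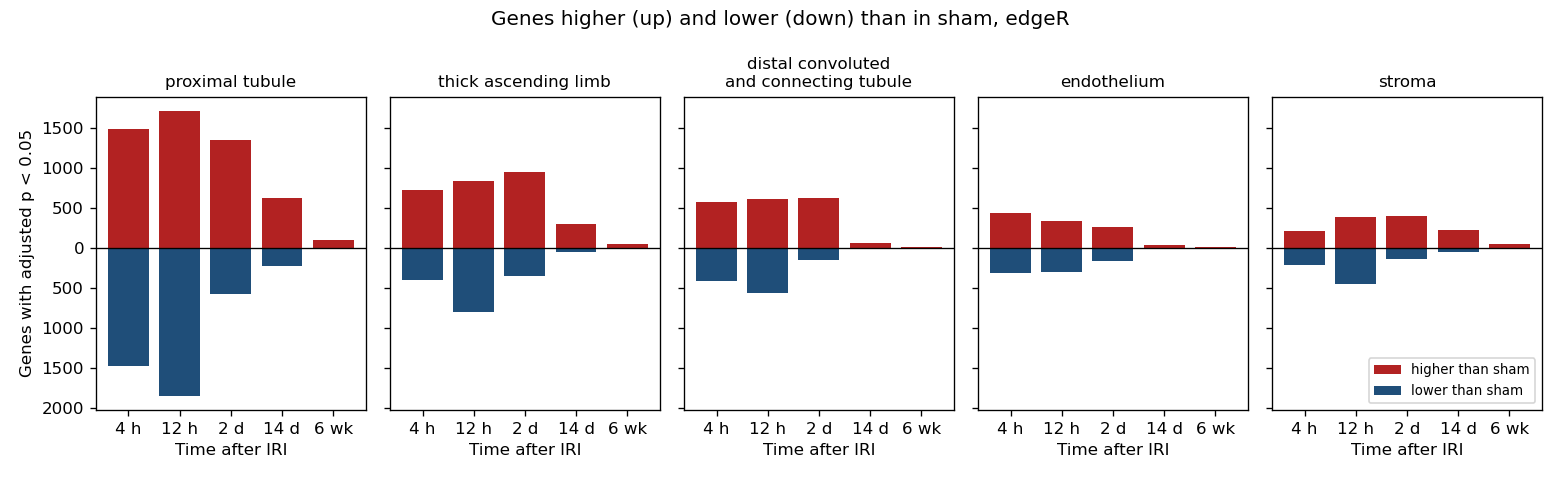
Number of genes higher than sham (bars up) and lower than sham (bars down) at an edgeR adjusted p under 0.05, by time after IRI and cell class, with 3 replicates in each group. Proximal tubule had 1718 higher and 1853 lower genes at 12 hours and 105 higher and 12 lower at 6 weeks.

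Some of the genes named lie, in GRCm38 (mm10) with GENCODE vM21 gene bounds, as follows. Havcr1 spans chromosome 11 from 46735080 to 46779578, Krt20 chromosome 11 from 99428403 to 99438150 and Top2a chromosome 11 from 98992943 to 99024189. Slc34a1 spans chromosome 13 from 55398187 to 55415592, and Vcam1 chromosome 3 from 116109949 to 116129688. Slc12a1 spans chromosome 2 from 125152505 to 125230002, Lcn2 chromosome 2 from 32384633 to 32388252 and Egf chromosome 3 from 129677565 to 129755316. Wnk1 spans chromosome 6 from 119923969 to 120038672, Klhl3 chromosome 13 from 58000228 to 58113592 and Col1a1 chromosome 11 from 94936224 to 94953042. All are annotated as protein-coding, and values are of whole genes, with reads of exons and introns not told apart here.

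At 4 hours the transporters of proximal tubule fell and injury, stress and early response genes rose. Slc34a1, the sodium-phosphate cotransporter of the brush border, fell from 21830 ± 2936 to 838 ± 717 CPM (counts per 1e6 UMIs of the tested genes of the class, scaled by TMM factors, mean ± SD, n = 3 in each group here and below). Its log2 change was -4.70 ± 0.69 (SE, edgeR adjusted p = 0.00026). Values given below for immune nuclei and podocytes, and medians over other classes, are another measure, CPM pooled over all nuclei of the group. Havcr1, which encodes kidney injury molecule 1, rose from 0.907 ± 0.730 to 196 ± 131 CPM (7.44 ± 1.02, edgeR adjusted p = 0.00015). Krt20, a keratin, rose from 0.204 ± 0.235 to 372 ± 132 CPM, by 10.78 ± 0.59 on the log2 scale (edgeR adjusted p = 1.6e-10).

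Of 25 members of the transport list, 17 fell, and 21 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.6e-12, and adjusted p = 0.065 with an estimated correlation). They included the endocytic receptor Lrp2, which fell from 7743 ± 2372 to 1784 ± 375 CPM (-2.12 ± 0.29), the proton exchanger Slc9a3 (-2.28 ± 0.25) and the dicarboxylate transporter Slc13a3 (-3.02 ± 0.33), at edgeR adjusted p values of 9.9e-07 to 1.3e-05. Slc5a12 fell by 3.87 and the amino acid transporter Slc7a13, a marker of the last segment, by 6.83. Among 24 tubular injury genes 15 rose, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.7e-11). Plaur, the urokinase receptor, rose from 2.75 ± 1.41 to 209 ± 80.8 CPM and Krt8 from 0.684 ± 1.19 to 89.1 ± 29.3. In this list 14 of 24 members had a mean CPM over 5 times higher in another class than in proximal tubule.

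Immediate early genes, the transcription factors that answer a stimulus within minutes, rose for 17 of 22 members at 4 hours, and for 20 adjusted over the list alone (camera adjusted p = 5e-16). Examples were Klf6 (5.59 ± 0.43), Jun (5.65 ± 0.50) and Fosl1 (5.88 ± 0.52). Targets of NRF2, the factor of the oxidant response, rose for 18 of 20 members, and for 19 adjusted over the list alone (camera adjusted p = 1.6e-15). Txnrd1, thioredoxin reductase, rose from 8.23 ± 2.91 to 304 ± 72.2 CPM, and Nqo1 from 9.71 ± 2.60 to 146 ± 15.7. Heat shock and protein folding genes rose for 13 of 20 members, in both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 2.7e-10, and adjusted p = 0.083 with an estimated correlation). The chaperone Hsp90ab1 rose from 7.65 ± 4.04 to 208 ± 42.6 CPM and Hspb1 from 1.496 ± 0.909 to 47.1 ± 18. Of the unfolded protein and integrated stress response 9 of 20 members rose, and 9 adjusted over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.24 with an estimated correlation). They included Trib3 (6.79 ± 0.69) and Asns, asparagine synthetase (4.46 ± 0.66). Targets of p53 rose for 8 of 20 members, and 9 adjusted over the list alone (camera adjusted p = 9.9e-06), with the cell cycle inhibitor Cdkn1a at 0.660 ± 0.950 in sham and 119 ± 13.5 CPM at 4 hours. NF-kB and chemokine genes rose for 12 of 20 members, and 15 adjusted over the list alone (camera adjusted p = 5.2e-09, and adjusted p = 0.069 with an estimated correlation). The neutrophil attractant Cxcl1 rose from 1.21 ± 0.735 to 123 ± 42.0 CPM. In total 1492 genes rose and 1484 fell, and no replicate left out moved the count by more than 1.5 times.

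By 12 hours more transport genes were below sham. Slc34a1 was down to 148 ± 33.7 CPM (-7.21 ± 0.77, edgeR adjusted p = 1.3e-05) and Lrp2 to 894 ± 27.5 CPM (-3.12 ± 0.30, edgeR adjusted p = 1.1e-07). Of the transport list 23 of 25 members fell, and 24 adjusted over the list alone (camera adjusted p = 2e-17). Slc6a19, the neutral amino acid transporter, fell from 354 ± 28.3 to 56.8 ± 10.9 CPM. Havcr1 rose to 586 ± 92.1 CPM (9.03 ± 1.07, edgeR adjusted p = 3.1e-05), against 241 CPM in immune nuclei and a median of 82.0 CPM over the other classes. Injury genes rose for 17 of 24 members, and 18 adjusted over the list alone (camera adjusted p = 9.7e-16). Lcn2, which encodes the iron-binding lipocalin NGAL, rose to 52.2 ± 4.76 CPM, below the 456 CPM of immune nuclei and the median of 189 CPM over other classes. Ftl1, a ferritin chain, rose from 1.34 ± 0.719 to 496 ± 94.1 CPM, against 749 CPM in immune nuclei.

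Immediate early genes rose for 19 of 22 members at 12 hours, in the count over all genes and in that adjusted over the list alone (camera adjusted p = 1.5e-16). Jun stood at 244 ± 49.8 CPM and Klf6 at 183 ± 14.2 CPM, against 2.33 ± 1.16 and 2.41 ± 2.08 in sham. Heat shock genes rose for 12 of 20 members, and 12 adjusted over the list alone (camera adjusted p = 3.9e-09, and adjusted p = 0.10 with an estimated correlation). Hspa8 rose from 15.4 ± 5.87 to 380 ± 61.8 CPM and Hspb1 by 6.01 ± 0.56. NRF2 targets rose for 15 and fell for 1 of 20 members, and 16 and 1 adjusted over the list alone (camera adjusted p = 1.5e-10). Fatty acid oxidation, the main fuel pathway of this segment, had 7 of 25 members lower, and 7 adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.45 with an estimated correlation). Crot fell from 269 ± 28.3 to 52.2 ± 2.61 CPM, and the regulators Ppara and Ppargc1a fell by 1.77 and 1.13 on the log2 scale. The call of this list was lost without sham replicate 1 and without replicate 1 at 12 hours. In total 1718 genes rose and 1853 fell.

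**Figure D2:**
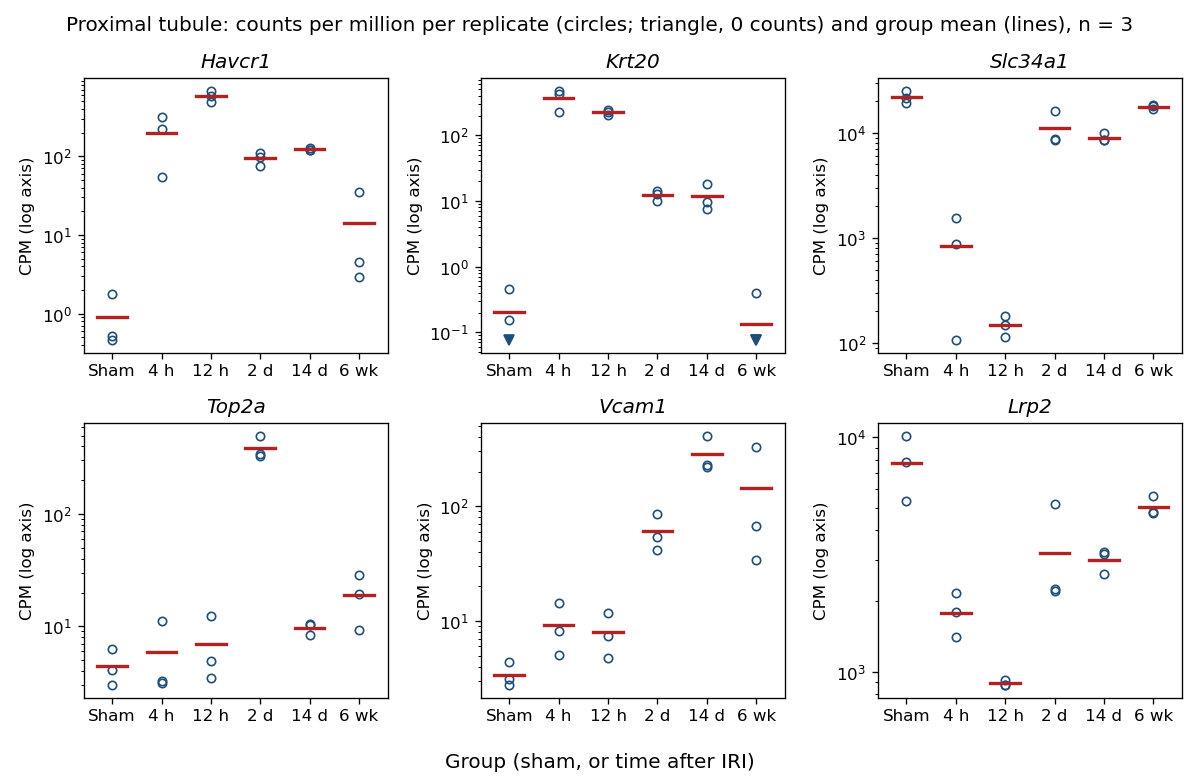
CPM of 6 genes in proximal tubule for each replicate (circles, with triangles for replicates at 0 counts) and group mean (lines) on log axes, by group, with 3 replicates in each. Slc34a1 was lowest at 12 hours (148 CPM) and stood at 17700 CPM at 6 weeks, and Vcam1 was highest at 14 days (287 CPM).

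At 2 days the genes of cell division had risen. Top2a, the topoisomerase of dividing cells, rose from 4.46 ± 1.69 to 391 ± 92.2 CPM (6.39 ± 0.56, edgeR adjusted p = 1.4e-06), and the mitotic motor Kif11 from 4.12 ± 1.15 to 176 ± 78.8 CPM. Of 29 measured cell cycle genes 25 rose, and 27 adjusted over the list alone (camera adjusted p = 7.1e-24). Cenpe (4.49 ± 0.56), the DNA repair enzyme Neil3 (7.13 ± 0.82) and the replication factor Ticrr (7 ± 0.70) rose too. Of 24 injury genes 19 rose, in both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 5.1e-17), with Havcr1 at 94.2 ± 17.8 CPM and Vcam1, a cell adhesion molecule, at 60.6 ± 22.9 (4.17 ± 0.74). S100a6, a calcium-binding protein at 0 counts in every sham replicate, was at 704 ± 719 CPM, at least 2324-fold higher against a floor of 3 counts over the group. Pooled over all nuclei of the group, S100a6 was at 286 CPM in proximal tubule. On that pooled measure its median over the other classes was 1182 CPM, and immune nuclei held 2467. Its mean CPM was over 5 times higher in another class. With the large libraries alone the log2 change of S100a6 was 10.67 against 14.98, that of Kif11 4.76 against 5.38 and that of Neil3 6.54 against 7.13.

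Transport genes fell for 8 and rose for 1 of 25 members at 2 days, and 13 and 1 adjusted over the list alone (camera adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation). The organic anion transporter Slc22a7 fell from 54.1 ± 9.56 to 0.305 ± 0.528 CPM and Lrp2 to 3215 ± 1717. With the large libraries alone their log2 changes were -5.88 against -6.56 and -0.60 against -1.27. Slc34a1 stood at 11030 ± 4241 CPM (-0.98 ± 0.59, edgeR adjusted p = 0.30) and Slc5a12 at 8214 ± 3091 (0.14 ± 0.63, edgeR adjusted p = 0.90). Of 20 NF-kB and chemokine genes 11 rose, and 16 adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.070 with an estimated correlation). NRF2 targets rose for 10 and fell for 1 of 20, and 14 and 1 adjusted over the list alone (camera adjusted p = 4e-05, and adjusted p = 0.068 with an estimated correlation). In total 1356 genes rose and 579 fell, 1935 together. The total was 1164, 1283, 3301, 1185 and 1208 without sham 2, sham 3, and replicates 1, 2 and 3 at 2 days. Without replicate 1 at 2 days 1757 rose and 1544 fell, and without replicate 2 946 and 239. It was 541 with the large libraries alone, where the calls of Lrp2, Cyp7b1, Slc17a3, Aqp1 and Taldo1 were lost. The log2 changes of the last 4 were -4.99, -1.06, -1.87 and 1.34 there, against -6.41, -1.69, -2.61 and 1.76.

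At 14 days NF-kB genes, Vcam1 and the injury list stood out. Vcam1 rose from 3.41 ± 0.831 to 287 ± 107 CPM (6.40 ± 0.80, edgeR adjusted p = 0.00022), against 172 CPM in immune nuclei, and Havcr1 to 122 ± 2.75 CPM (6.77 ± 1.00, edgeR adjusted p = 0.0013). Of the NF-kB and chemokine list 16 of 20 members rose, and 17 adjusted over the list alone (camera adjusted p = 2e-19). Birc3, an inhibitor of apoptosis, rose from 11.5 ± 2.65 to 134 ± 26.3 CPM, the NF-kB subunit Relb from 5.13 ± 1.36 to 54.1 ± 5.98 and Nfkb1 from 24.1 ± 8.11 to 92.4 ± 20.4. The chemokine Cxcl2 rose to 23.5 ± 5.23 CPM (8.47 ± 1.07). Injury genes rose for 15 of 24, and 18 adjusted over the list alone (camera adjusted p = 8.7e-20), among them Cdh6, a cadherin of nephron development (3.50 ± 0.39), and Cd44 (4.46 ± 0.63). Both had a mean CPM over 5 times higher in another class, and Cd44 was at 5.41 with the large libraries alone.

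Transport genes at 14 days fell for 6 and rose for 1 of 25 members, and 10 and 1 adjusted over the list alone (camera adjusted p = 2e-07, and adjusted p = 0.15 with an estimated correlation). Slc6a19 fell from 354 ± 28.3 to 75.6 ± 8.89 CPM and Lrp2 to 2998 ± 343. Slc34a1 was at 9002 ± 724 CPM (-1.28 ± 0.60, edgeR adjusted p = 0.25). Col19a1, a collagen gene, fell from 98.8 ± 17.02 to 8.50 ± 4.50 CPM. In total 620 genes rose and 223 fell, 843 together. The total was 465, 533 and 484 without sham 2, sham 3 and replicate 3 at 14 days, and 480 with the large libraries alone, where Lrp2 was no longer past the threshold (log2 change -1.22 against -1.37, with fewer replicates).

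At 6 weeks 105 genes rose and 12 fell in proximal tubule. Vcam1 was at 143 ± 161 CPM (5.41 ± 0.77, edgeR adjusted p = 0.0027), and the monocyte attractant Ccl2 rose from 0.851 ± 0.827 to 65.7 ± 85.1 CPM (6.38 ± 1.05, edgeR adjusted p = 0.006), a call lost without sham replicate 1 and with the same number of nuclei. Slc34a1 was at 17700 ± 676 CPM (-0.30 ± 0.59, edgeR adjusted p = 0.89) and Havcr1 at 14.3 ± 18.4 CPM (3.68 ± 0.95, edgeR adjusted p = 0.12). Replicate 3 carried most of the means of Vcam1 and Havcr1: in replicates 1, 2 and 3 Vcam1 was at 34.2, 67.5 and 328.5 CPM and Havcr1 at 2.88, 4.50 and 35.5. Without it the log2 changes of Vcam1, Ccl2 and Havcr1 were 3.88, 4.33 and 1.56. With only the 2 groups in the fit Vcam1 and Ccl2 did not pass (edgeR adjusted p = 0.058 and 0.13). Mro fell from 136 ± 4.56 to 25.7 ± 4.80 CPM and the carboxylesterase Ces1d from 67.0 ± 33.7 to 8.71 ± 2.34. In the injury list 5 of 24 members rose, and 8 adjusted over the list alone (camera adjusted p = 7.8e-11). Of 20 NF-kB and chemokine genes 2 rose, and 13 adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.070 with an estimated correlation). The total of 117 genes became 69, 50, 37, 73, 416 and 47 without sham 1, sham 2, sham 3, replicate 3 at 12 hours, and replicates 1 and 3 at 6 weeks. It was 70 with the large libraries alone, 9 with only the 2 groups in the fit, 271 in DESeq2, 63 with the same number of nuclei and 54 without possible free RNA genes.

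In thick ascending limb at 4 hours Slc12a1, the sodium-potassium-chloride cotransporter and target of loop diuretics, fell from 24270 ± 2486 to 4848 ± 1101 CPM (-2.32 ± 0.17, edgeR adjusted p = 1.5e-08), and the growth factor Egf from 4650 ± 984 to 132 ± 72.1 CPM (-5.12 ± 0.58, edgeR adjusted p = 2.8e-05). Umod, the uromodulin gene, was at 289 ± 81.4 in sham and 128 ± 63.1 CPM (-1.15 ± 0.37, edgeR adjusted p = 0.059). Of 22 function genes 8 fell and 1 rose, and 10 and 1 adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.12 with an estimated correlation). Lcn2, at 0 counts in sham, was at 86.8 ± 75.6 CPM, at least 175-fold higher against 3 counts over the group, with 47.0 CPM in immune nuclei. Its log2 change was 10.29, and 10.95 with the large libraries alone. Ppef1, a phosphatase gene, rose from 2.42 ± 1.28 to 321 ± 38.0 CPM and Il34, a macrophage growth factor, from 132 ± 41.8 to 1705 ± 260.

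Injury genes rose for 14 and fell for 1 of 24 members in thick ascending limb at 4 hours, and 18 and 1 adjusted over the list alone (camera adjusted p = 2.2e-08), with Myc at 65.2 ± 4.06 CPM against 9.18 ± 0.678 in sham. Here too 14 of 24 members had a mean CPM over 5 times higher in another class. Of 15 NF-kB and chemokine genes 8 rose, and 10 adjusted over the list alone (camera adjusted p = 5.5e-08), and immediate early genes for 12 of 20, and 13 adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.088 with an estimated correlation). Egr2 rose by 5.60 ± 0.93 and Fos by 5.17 ± 1.03. Heat shock genes did not pass the list test here (camera adjusted p = 0.76). Dnajb4, a co-chaperone, fell from 60.2 ± 6.24 to 10.7 ± 2.53 CPM, a call lost without replicate 1 at 4 hours, and Hspb1 was at 16.2 ± 12.7 against 5.63 ± 6.38 CPM in sham. In total 723 genes rose and 404 fell, 1127 together, and 706 and 731 without sham 2 and sham 3.

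At 12 hours Slc12a1 was down to 1152 ± 221 CPM (-4.40 ± 0.19, edgeR adjusted p = 1e-12) and Egf to 13.02 ± 1.98 CPM (-8.46 ± 0.68, edgeR adjusted p = 7.3e-07). Umod was at 215 ± 20.8 CPM, against 289 ± 81.4 in sham (-0.43 ± 0.36, edgeR adjusted p = 0.52). Of 22 function genes 13 fell, and 14 adjusted over the list alone (camera adjusted p = 3e-13). Medullary nuclei were 1713 of 2303, 647 of 972 and 663 of 967 in this class at 12 hours, by replicate. In sham they were 1089 of 2276, 470 of 896 and 418 of 837. How far this mix of nuclei bears on the falls was not tested. The prostaglandin receptor Ptger3 fell from 815 ± 89.8 to 129 ± 6.81 CPM. The kinase Wnk1 fell from 1568 ± 268 to 276 ± 14.4 CPM, and its mean CPM was over 5 times higher in another class, with 16550 in sham distal convoluted and connecting tubule. Lcn2 rose to 226 ± 25.9 CPM and Clu, which encodes clusterin, from 2.84 ± 0.159 to 221 ± 12.8, against 456 and 335 CPM in immune nuclei. Their medians over the other classes were 167 and 198 CPM, and the mean CPM of Clu was over 5 times higher in another class. Free RNA as a source of these transcripts in thick ascending limb was not tested. In the injury list 16 of 24 members rose and 2 fell, and 18 and 2 adjusted over the list alone (camera adjusted p = 3e-13). The NF-kB and chemokine list rose for 11 of 15, and 12 adjusted over the list alone (camera adjusted p = 7.6e-07), and NRF2 targets for 7 of 18, and 10 adjusted over the list alone (camera adjusted p = 4.2e-05). Gclc, the glutathione synthesis enzyme, rose from 23.5 ± 10.3 to 748 ± 57.9 CPM. In total 841 genes rose and 798 fell, 1639 together, and 1074 and 1015 without sham 2 and replicate 1 at 12 hours.

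Later, Slc12a1 in thick ascending limb was at 15460 ± 1935 CPM at 2 days (-0.65 ± 0.17, edgeR adjusted p = 0.013), 16750 ± 696 at 14 days (-0.54 ± 0.16, edgeR adjusted p = 0.089) and 25150 ± 2067 at 6 weeks (0.05 ± 0.16, edgeR adjusted p = 0.95). The 2-day call was lost without replicate 2 or 3 at 2 days and with the large libraries alone (-0.43). Egf was at 201 ± 162 CPM at 2 days (-4.52 ± 0.56, edgeR adjusted p = 1e-04), and function genes fell for 7 and rose for 1 of 22, and 10 and 1 adjusted over the list alone (camera adjusted p = 3.8e-05, and adjusted p = 0.18 with an estimated correlation). Cell cycle genes rose for 6 of 18 at 2 days, and 9 adjusted over the list alone (camera adjusted p = 5.7e-05, and adjusted p = 0.070 with an estimated correlation). Top2a rose from 2.42 ± 1.28 to 40.5 ± 19.6 CPM, against 353 in immune nuclei and a median of 121 CPM over other classes, and its mean CPM was over 5 times higher in another class. With the large libraries alone Top2a was at 2.76 against 3.90 on the log2 scale and Egf at -3.56 against -4.52. Injury genes rose for 12 of 24 at 2 days, 7 at 14 days and 1 at 6 weeks, and for 17, 14 and 3 adjusted over the list alone (camera adjusted p = 3.9e-11, 5.5e-09 and 1.6e-05). NF-kB and chemokine genes rose for 3 of 15 at 14 days, and 5 adjusted over the list alone (camera adjusted p = 0.00077, and adjusted p = 0.11 with an estimated correlation).

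At 14 days Arhgap36 in thick ascending limb was at 0 counts in sham and 39.4 ± 20.3 CPM (at least 44.7-fold, against 3 counts over the group). The synaptotagmin Syt2 rose from 2.51 ± 0.463 to 247 ± 71.7 CPM. At 6 weeks Dcdc2a, a gene of the ciliary axis, rose from 14.04 ± 4.70 to 415 ± 419 CPM (4.87 ± 0.66, edgeR adjusted p = 0.0029), and by 3.60 on the log2 scale without replicate 3 at 6 weeks. Podocytes held 503 CPM of Dcdc2a at 6 weeks, and its median over the other classes was 177 CPM. Genes that rose and fell numbered 957 and 348 at 2 days, 300 and 54 at 14 days and 49 and 1 at 6 weeks. The 2-day total of 1305 was 721, 692, 2810, 726 and 835 without sham 2, sham 3, and replicates 1, 2 and 3 at 2 days, and 426 with the large libraries alone. Without replicate 1 at 2 days 1495 rose and 1315 fell. The 14-day total of 354 was 132, 112, 766, 133 and 171 without sham 2, sham 3, and replicates 1, 2 and 3 at 14 days, and 50 with the large libraries. The 6-week total of 50 was 32, 14, 15, 267 and 18 without sham 1, 2 and 3, and replicates 1 and 3 at 6 weeks, 32 with the large libraries, 11 with only the 2 groups in the fit and 111 in DESeq2.

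In distal convoluted and connecting tubule Klhl3, an adaptor that marks WNK kinases for degradation, fell from 2585 ± 230 to 149 ± 66.7 CPM at 4 hours (-4.09 ± 0.35, edgeR adjusted p = 4e-08), and Wnk1 from 16550 ± 2563 to 3329 ± 1422 CPM (-2.31 ± 0.27, edgeR adjusted p = 2e-06). At 12 hours they were at 124 ± 14.03 and 665 ± 49.2 CPM. Kl, which encodes klotho, fell from 944 ± 149 to 168 ± 5.22 CPM at 4 hours and 89.5 ± 5.96 CPM at 12 hours. Slc12a3, the thiazide-sensitive cotransporter, was at 6130 ± 1544 CPM in sham, 3692 ± 442 at 4 hours (-0.73 ± 0.26, edgeR adjusted p = 0.085) and 2124 ± 139 at 12 hours (-1.53 ± 0.26, edgeR adjusted p = 0.00024). The magnesium channel Trpm7 fell from 4171 ± 579 to 847 ± 61.7 CPM at 12 hours, and Pvalb from 88.5 ± 21.2 to 0.907 ± 0.801. Function genes fell for 10 and rose for 2 of 25 at 4 hours, and 12 and 2 adjusted over the list alone (camera adjusted p = 5.1e-07, and adjusted p = 0.16 with an estimated correlation). At 12 hours 18 of 25 fell, and 19 adjusted over the list alone (camera adjusted p = 1.1e-21).

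NF-kB and chemokine genes in this class rose for 11 of 12 members at 4 hours, and 12 adjusted over the list alone (camera adjusted p = 1.2e-11), and for 7 at 12 hours, and 8 adjusted over the list alone (camera adjusted p = 2.8e-07). Relb rose from 6.92 ± 3.99 to 153 ± 31.6 CPM at 4 hours and Birc3 from 26.04 ± 6.63 to 239 ± 65.4. Lif, a cytokine of the interleukin 6 family at 0 counts in sham, was at 48.7 ± 9.30 CPM, at least 74.4-fold higher against 3 counts over the group. Clu rose from 4.29 ± 5.55 to 342 ± 163 CPM at 4 hours. Injury genes rose for 12 of 20 at 4 hours, 15 at 12 hours, 13 at 2 days, 4 at 14 days and 1 at 6 weeks. Adjusted over the list alone 14, 15, 15, 12 and 1 rose (camera adjusted p = 3.6e-11, 2e-15, 8.1e-13, 1.3e-08 and 0.029). The 6-week call gave adjusted p = 0.27 with an estimated correlation and was lost without several single replicates. In this list 12 of 20 members had a mean CPM over 5 times higher in another class.

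At 2 days Klhl3 was at 392 ± 174 CPM and Wnk1 at 3624 ± 1545. Their log2 changes were -2.72 and -2.19, and -2.11 and -1.60 with the large libraries alone. Function genes fell for 10 and rose for 1 of 25, and 11 and 1 adjusted over the list alone (camera adjusted p = 7.4e-08, and adjusted p = 0.13 with an estimated correlation). Cell cycle genes rose for 5 of 14, and 8 adjusted over the list alone (camera adjusted p = 2.1e-05), among them Kif23, from 11.4 ± 4.06 to 46.1 ± 6.20 CPM. At 6 weeks the clock gene Npas2 rose from 3.79 ± 1.72 to 51.6 ± 16.4 CPM (3.61 ± 0.57, edgeR adjusted p = 0.013), a call lost without sham 2 or sham 3. Genes that rose and fell numbered 570 and 419 at 4 hours, 617 and 562 at 12 hours, 629 and 146 at 2 days, 57 and 3 at 14 days and 9 and 0 at 6 weeks. At 6 weeks 507 of 11194 tested genes had an unadjusted p under 0.05 in edgeR, no more than chance alone would give. DESeq2 called 32 higher and 1 lower. The 4-hour total of 989 was 628 and 647 without sham 2 and 3, and the 12-hour total of 1179 was 724 without replicate 1 at 12 hours and 1974 with the large libraries. The 2-day total of 775 was 391, 401, 1798 and 387 without sham 2, sham 3, and replicates 1 and 2 at 2 days, and 277 with the large libraries. Without replicate 1 at 2 days 968 rose and 830 fell. The 14-day total of 60 was 11, 9, 183, 18 and 15 without sham 2, sham 3, and replicates 1, 2 and 3 at 14 days, and 6 with the large libraries. The 6-week total of 9 was 4, 4, 0, 14, 34 and 4 without sham 1, 2 and 3, replicate 1 at 4 hours, and replicates 1 and 2 at 6 weeks.

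In endothelium at 4 hours Ccl2 rose from 0.835 ± 1.45 to 210 ± 66.0 CPM (7.89 ± 1.10, edgeR adjusted p = 5.9e-05), against 26.9 CPM in immune nuclei. Vcam1, the leukocyte adhesion receptor, rose from 80.6 ± 23.2 to 402 ± 71.8 CPM (2.29 ± 0.38, edgeR adjusted p = 0.00035). The basement membrane collagen Col4a1 rose from 212 ± 37.6 to 1100 ± 551 CPM. Npr3, a natriuretic peptide receptor, fell from 102 ± 23.2 to 4.67 ± 4.07 CPM, and Flt1 was at 2643 ± 914 and 2412 ± 492 CPM (-0.13 ± 0.26, edgeR adjusted p = 0.86). Emcn fell from 1227 ± 235 to 700 ± 135 CPM (-0.81 ± 0.23, edgeR adjusted p = 0.034). With the large libraries alone its log2 change was -0.85 (edgeR adjusted p = 0.1). Endothelial activation genes rose for 6 of 13, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00042, and adjusted p = 0.11 with an estimated correlation). They included the protease Adamts4 (4.67 ± 0.81) and the growth factor Hbegf (3.17 ± 0.60). Matrix genes rose for 7 of 19, and 10 adjusted over the list alone (camera adjusted p = 1.3e-06). The NF-kB and chemokine list rose for 5 of 13, and 6 adjusted over the list alone (camera adjusted p = 4.9e-07), and immediate early genes for 8 of 19, and 10 adjusted over the list alone (camera adjusted p = 4.4e-06, and adjusted p = 0.075 with an estimated correlation).

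At 12 hours Vcam1 was at 339 ± 73.3 CPM in endothelium (2.04 ± 0.37, edgeR adjusted p = 0.0014), and the vasoconstrictor gene Edn1 rose from 2.39 ± 4.14 to 51.7 ± 7.24 CPM (3.66 ± 0.64, edgeR adjusted p = 0.001). Activation genes rose for 4 of 13, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation). Tubular injury genes rose in endothelium for 11 of 24 at 4 hours, 16 at 12 hours and 3 at 14 days, and at 2 days 7 rose and 1 fell. Adjusted over the list alone 17, 16, 8 and 15 rose, with 1 lower at 4 hours, 12 hours and 2 days (camera adjusted p = 1.5e-09, 1.9e-16, 1.3e-06 and 5.7e-08). At 12 hours Lcn2 was at 303 ± 77.8 CPM in endothelium, 456 in immune nuclei and a median of 167 over the other classes, and Havcr1 at 91.5 ± 18.7, 241 and 82.0. The median of Vcam1 over the other classes was 10.7 CPM, with 113 in immune nuclei. Transcripts of proximal tubule fell in endothelium at 12 hours for 5 of 20 members, and 11 adjusted over the list alone (camera adjusted p = 2.2e-08). Slc5a12 fell from 259 ± 145 to 8.25 ± 9.71 CPM and Slc7a13 from 122 ± 56.3 to 6.38 ± 5.87.

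At 2 days cell cycle genes rose in endothelium for 8 of 13, and 11 adjusted over the list alone (camera adjusted p = 7.9e-07), with Mki67 at 2.93 ± 0.575 in sham and 47.2 ± 13.1 CPM. With the large libraries alone Mki67 passed, and Kif11, Ccnb2 and Cenpf did not, at log2 changes of 2.98, 3.06 and 3.36 against 3.03, 3.05 and 3.59. Matrix genes rose for 6 of 19, and 9 adjusted over the list alone (camera adjusted p = 1.3e-06), and 9 of the 19 had a mean CPM over 5 times higher in another class. They included Acta2, smooth muscle actin, from 4.07 ± 1.21 to 74.4 ± 57.1 CPM, with a log2 change of 4.08, and 2.98 with the large libraries alone. At 6 weeks Vcam1 was at 266 ± 105 CPM (1.70 ± 0.37, edgeR adjusted p = 0.069). The injury list passed its test at 6 weeks (camera adjusted p = 0.017, and adjusted p = 0.22 with an estimated correlation), with 4 members higher adjusted over the list alone, and did not without replicate 1 at 6 weeks. Genes that rose and fell numbered 435 and 312 at 4 hours, 335 and 301 at 12 hours, 269 and 160 at 2 days, 38 and 14 at 14 days and 8 and 1 at 6 weeks. The 12-hour total of 636 was 422, 346 and 338 without sham 1, 2 and 3, and 285, 393 and 353 without replicates 1, 2 and 3 at 12 hours. With the large libraries it was 1228. The 2-day total of 429 was 200, 171, 1309, 177 and 259 without sham 2, sham 3, and replicates 1, 2 and 3 at 2 days, and 127 with the large libraries. Without replicate 1 at 2 days 564 rose and 745 fell. The 14-day total of 52 was 21, 1 and 1 without sham 1, 2 and 3, and 103, 13 and 8 without replicates 1, 2 and 3 at 14 days. It was 26, 25 and 31 without replicates 1, 2 and 3 at 12 hours, 33 without replicate 3 at 2 days and 11 with the large libraries. The 6-week total of 9 was 0, 0, 122, 5 and 3 without sham 2, sham 3, and replicates 1, 2 and 3 at 6 weeks, 19 with the large libraries, 29 in DESeq2 and 1 with only the 2 groups in the fit.

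In stroma at 4 hours Il6 rose from 2.77 ± 4.79 to 240 ± 71.7 CPM (6.82 ± 0.94, edgeR adjusted p = 1.8e-05), Ccl2 from 11.3 ± 12.4 to 329 ± 35.7 CPM (4.34 ± 0.76, edgeR adjusted p = 0.00052) and the macrophage growth factor Csf1 from 8.15 ± 1.36 to 183 ± 85.2 CPM. Tnc, which encodes tenascin C, rose from 69.4 ± 38.3 to 847 ± 433 CPM at 4 hours (3.68 ± 0.43, edgeR adjusted p = 1.6e-06) and 1694 ± 113 at 12 hours (4.67 ± 0.44, edgeR adjusted p = 3e-08). Col1a1, the main fibrillar collagen, was at 48.0 ± 19.1 CPM in sham, 18.2 ± 6.67 at 4 hours (-1.32 ± 0.69, edgeR adjusted p = 0.32) and 16.01 ± 13.5 at 12 hours (-1.70 ± 0.57, edgeR adjusted p = 0.046). It rose to 612 ± 45.6 at 2 days (3.64 ± 0.44, edgeR adjusted p = 1.2e-05) and 190 ± 2.58 CPM at 14 days (1.96 ± 0.45, edgeR adjusted p = 0.0083). The 12-hour call was lost without most single replicates, and the 14-day call without sham 1 or sham 3 and with the large libraries alone, where the log2 change was 2.02 with fewer replicates. At 6 weeks Col1a1 was at 145 ± 90.6 CPM (1.64 ± 0.45, edgeR adjusted p = 0.078). Pdgfrb was at 428 ± 54.0 CPM in sham and 696 ± 127 at 2 days (0.71 ± 0.32, edgeR adjusted p = 0.19).

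Matrix and myofibroblast genes in stroma rose for 6 and fell for 1 of 22 at 4 hours, 6 and 1 at 12 hours, and 13 and 1 at 2 days. They rose for 6 at 14 days and 3 at 6 weeks. Adjusted over the list alone 7, 7, 15, 8 and 7 rose, with 3, 2 and 1 lower at 4 hours, 12 hours and 2 days. The list passed at each of these times (camera adjusted p = 0.050, 0.00018, 1.5e-10, 2.7e-05 and 1.6e-06), against adjusted p = 0.58, 0.35, 0.16, 0.33 and 0.27 with an estimated correlation, and its 4-hour call was lost with the large libraries and without several single replicates. Col8a1 rose from 58.9 ± 30.8 to 593 ± 152 CPM at 12 hours and 800 ± 119 at 2 days, and Col3a1 from 129 ± 17.7 to 1099 ± 191 at 2 days. Cell cycle genes rose for 2 of 5 at 2 days, and 5 adjusted over the list alone (camera adjusted p = 2.6e-05), with Top2a at 7.77 ± 9.84 in sham and 438 ± 84.2 CPM. NF-kB and chemokine genes rose for 5 of 11 at 4 hours, and 6 adjusted over the list alone (camera adjusted p = 2e-06). Immediate early genes rose for 3 of 10 at 4 hours, and 3 adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.43 with an estimated correlation). Heat shock genes rose for 5 of 17 at 12 hours, and 7 adjusted over the list alone (camera adjusted p = 0.0015, and adjusted p = 0.22 with an estimated correlation), with Hsp90aa1 rising from 15.5 ± 3.93 to 340 ± 76.0 CPM.

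Tubular injury genes in stroma rose for 11 of 21 at 4 hours, 14 at 12 hours, 8 at 2 days and 4 at 14 days, with 1 lower at 12 hours and 1 at 2 days. Adjusted over the list alone 14, 15, 12 and 5 rose and 1 fell at each of the 3 early times (camera adjusted p = 1.6e-09, 1.5e-10, 2.3e-06 and 0.00096). The 14-day call gave adjusted p = 0.15 with an estimated correlation. Myc rose from 8.15 ± 1.36 to 235 ± 59.8 CPM at 4 hours, and Lcn2, at 0 counts in sham, was at 285 ± 41.2 CPM at 12 hours, at least 66.9-fold higher against 3 counts over the group, with 456 CPM in immune nuclei and a median of 167 over the other classes. At these levels free RNA was not excluded as the source of such transcripts in stroma. Inhba, the activin A subunit, rose from 3.51 ± 4.30 to 156 ± 63.4 CPM at 14 days (5.39 ± 0.99, edgeR adjusted p = 0.0013), and Fbn2, a fibrillin, from 12.4 ± 14.4 to 233 ± 179 CPM at 6 weeks (4.42 ± 0.79, edgeR adjusted p = 0.0052), a call lost without sham 1 or replicate 3 at 6 weeks. Vcan, the proteoglycan versican, fell from 163 ± 112 to 6.27 ± 5.98 CPM at 6 weeks (-4.19 ± 0.75, edgeR adjusted p = 0.0047). Genes that rose and fell numbered 214 and 211 at 4 hours, 392 and 446 at 12 hours, 400 and 133 at 2 days, 231 and 49 at 14 days and 52 and 4 at 6 weeks. The 12-hour total of 838 was 522 and 516 without sham 1 and replicate 1 at 12 hours. The 2-day total of 533 was 220, 224, 245 and 353 without sham 2, sham 3, and replicates 2 and 3 at 2 days, and 157 with the large libraries. The 14-day total of 280 was 147, 142, 150 and 151 without sham 2, sham 3, and replicates 2 and 3 at 14 days, and 67 with the large libraries. The 6-week total of 56 was 23, 17, 17, 108 and 13 without sham 1, 2 and 3, and replicates 1 and 3 at 6 weeks.

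The responses of proximal tubule and thick ascending limb were compared directly, as the difference of list means of log2 CPM within each replicate. The SE was 0.22 for every list and time, as moderation left 1 variance for the 4 lists. Those lists came from the same replicates, so the limma p-values do not measure the spread of each list alone. Heat shock genes moved by 2.46 in proximal tubule and -0.26 in thick ascending limb at 4 hours, a difference of 2.71 ± 0.22 (SE, limma adjusted p = 2.5e-15, higher than every sham replicate in 3 of 3). At 12 hours they moved by 2.78 and 0.68, a difference of 2.11 ± 0.22 (limma adjusted p = 8e-12). Immediate early genes differed by 1.64 ± 0.22 at 4 hours and 1.94 ± 0.22 at 12 hours (limma adjusted p = 4.9e-09 and 7.1e-11), and at 2 days by 0.15 ± 0.22 (limma adjusted p = 0.50). Injury genes differed by 1.14, 1.32, 0.92 and 1.37 at 4 hours, 12 hours, 2 days and 14 days, each ± 0.22 (limma adjusted p = 9.8e-06, 6e-07, 0.00023 and 2.9e-07), and by 0.34 ± 0.22 at 6 weeks (limma adjusted p = 0.14). NF-kB and chemokine genes moved by 2.70 in proximal tubule and 1.00 in thick ascending limb at 14 days, a difference of 1.70 ± 0.22 (limma adjusted p = 2.5e-09). At 12 hours and 2 days they differed by 0.52 and 0.51 (limma adjusted p = 0.036 each). The 12-hour call was lost with the large libraries (0.41), with a prior count of 0.5 (0.37), without possible free RNA genes (0.43), and without sham 1 (0.43), sham 2 (0.49), replicates 2 and 3 at 12 hours (0.52 and 0.46) and replicate 1 at 2 days (0.50). The 2-day call was lost with the large libraries (0.42), with library size class as a term (0.47), with a prior count of 0.5 (0.41), without possible free RNA genes (0.29), and without sham 1 (0.42), sham 2 (0.48), replicate 2 at 12 hours (0.50) and replicates 1, 2 and 3 at 2 days (0.48, 0.52 and 0.51).

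**Figure D3:**
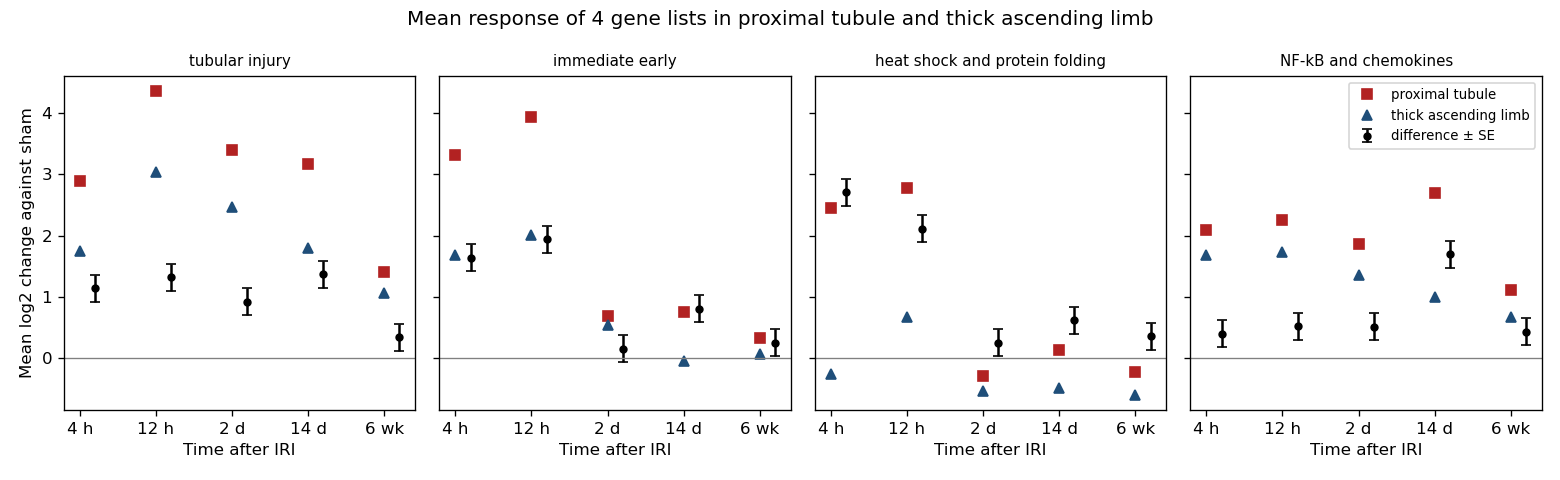
Mean log2 change against sham of 4 gene lists in proximal tubule (squares) and thick ascending limb (triangles), and their difference ± SE (circles), by time after IRI, with 3 replicates in each group. Heat shock genes at 4 hours were at 2.46 in proximal tubule and -0.26 in thick ascending limb.

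Shares of nuclei were compared to ask which cell classes were more or less frequent among the nuclei recovered. Thin limb nuclei fell from 5.54 ± 0.397% to 1.80 ± 1.01% at 4 hours (log2 change -1.59 ± 0.34, edgeR adjusted p = 0.019, lower than every sham replicate in 3 of 3). Podocytes, the filtering cells of the glomerulus, rose from 0.408 ± 0.112% to 0.948 ± 0.280% at 4 hours (1.11 ± 0.31, edgeR adjusted p = 0.049), and parietal epithelium rose from 0.264 ± 0.0457% to 0.681 ± 0.206% at 14 days (edgeR adjusted p = 0.034). Over 25 alternatives these adjusted p values ranged from 0.00037 to 0.15, 0.0091 to 0.47 and 0.012 to 0.17 and were under 0.05 in 20, 9 and 13. Proximal tubule made up 41.2 ± 0.756% in sham, 47.2 ± 3.22% at 4 hours (edgeR adjusted p = 0.53), 32.3 ± 0.287% at 12 hours (edgeR adjusted p = 0.32) and 36.5 ± 14.6% at 2 days (edgeR adjusted p = 0.57). At 2 days it was 53.4% in replicate 1 and 28.7% and 27.5% in replicates 2 and 3, which came from small libraries. Over 24 alternatives the adjusted p ranged from 0.031 to 0.48 at 12 hours and from 0.0084 to 0.99 at 2 days, each lowest without replicate 1 at 2 days, where alone it was under 0.05. The 2-day log2 change of -0.17 was reversed, at 0.37, with the large libraries alone (edgeR adjusted p = 0.14). Immune nuclei made up 1.95 ± 0.383% in sham, 3.53 ± 1.56% at 2 days, 4.68 ± 0.761% at 14 days and 4.51 ± 2.93% at 6 weeks (edgeR adjusted p = 0.29, 0.14 and 0.14). In replicates 1, 2 and 3 at 6 weeks the immune share was 2.98%, 2.67% and 7.9%. Endothelium made up 10.8 ± 0.646% in sham and 5.00 ± 1.39% at 14 days (edgeR adjusted p = 0.099). Over 25 alternatives its adjusted p ranged from 0.00013, with library size class as a term, to 0.37 and was under 0.05 in 6. At 12 hours, 2 days and 6 weeks 0 of 13 classes passed in edgeR, and 3, 1 and 5 had an unadjusted p under 0.05. The exact permutation test of 3 against 3 replicates cannot go below p = 0.1, the value it gave for thin limb and podocytes at 4 hours. Other classes were as fully separated from sham. At 12 hours the replicates of proximal tubule were at 32.35%, 32.56% and 31.99%, against 41.3%, 41.97% and 40.46% in sham. Those of thick ascending limb were at 20.5%, 20.69% and 21.35%, against 14.74%, 15.6% and 15.32%.

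Within proximal tubule the authors named 2 new states beside the 3 segments, and their shares were not tested because their defining genes move with injury. NewPT1 made up 1.56 ± 0.404% of proximal tubule nuclei in sham, 43.6 ± 21.8% at 4 hours, 39.9 ± 5.77% at 12 hours and 12.4 ± 5.73% at 2 days. NewPT2 made up 0.483 ± 0.0681% in sham, 3.57 ± 0.739% at 4 hours, 27.5 ± 2.92% at 14 days and 9.38 ± 8.79% at 6 weeks, where replicates ran from 3.37% to 19.5%. The third segment, PTS3, made up 17.5 ± 1.86% in sham, 5.50 ± 3.01% at 4 hours, 4.36 ± 1.83% at 2 days and 17.2 ± 10.1% at 6 weeks.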

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

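The comparison of responses was planned. The fits by library set, the tests of free RNA with a shared source and the splits of samples were added after data were seen, though bounds for the library set and for the shared-source rise were written before those values. The results listed first stood out because proximal tubule and thick ascending limb, 2 cell classes of the same replicates, differed in their response to the same injury. The list mean of injury genes rose more in proximal tubule by 1.14, 1.32, 0.92 and 1.37 on the log2 scale at 4 hours, 12 hours, 2 days and 14 days. Immediate early genes differed by 1.64, 1.94 and 0.81 at 4 hours, 12 hours and 14 days. Heat shock genes differed by 2.71, 2.11 and 0.62 at the same times, and NF-kB and chemokine genes by 0.52, 0.51 and 1.70 at 12 hours, 2 days and 14 days. In each case 3 of 3 injured replicates lay above every sham replicate. Proximal tubule held more UMIs, 1483252 to 17796598 per replicate against 516214 to 4662607 in thick ascending limb. The prior count of 2 thus stood for a higher CPM in thick ascending limb and held rises from near 0 counts down more there. With a prior count of 0.5, 17 of 20 differences kept their side of the threshold. Those of NF-kB and chemokine genes at 12 hours and 2 days lost their call. Immediate early genes at 2 days, which had not passed, turned direction. Heat shock and immediate early genes at 12 hours still passed (limma adjusted p = 6.9e-08 and 6.9e-06). A smaller prior count lessens this effect without removing it, so how much of the differences came from it was left open. Over 23 alternatives the adjusted p of the 14-day heat shock difference ranged from 0.0058 to 0.12, that of NF-kB genes from 0.016 to 0.24 at 12 hours and from 0.016 to 0.28 at 2 days.

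The heat shock difference at 4 hours could come from the larger number of proximal tubule nuclei or from the nuclei of the 2 new states. With the same number of nuclei in every replicate of a class it was 2.16, and without the new states 2.41, against 2.71 in all nuclei and a spread of 0.21. Each stayed above 0.5 of the reported value, the bound set beforehand against those causes. The draw took 535 nuclei per replicate in proximal tubule and 319 in thick ascending limb. It could not set aside the number of nuclei between the 2 classes, which stayed unequal. An earlier or stronger stress in the proximal tubule of injured kidneys remains open, and its cause was not tested.

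Small libraries were found at 2 and 14 days and not in sham, so the library set could stand behind changes at those times. With library size class as a term the median ratio of the log2 change to that without it, over the genes called in proximal tubule, was 0.92 at 2 days (quartiles 0.82 and 1.01) and 0.94 at 14 days (0.85 and 1.03). Of these genes 67.6% and 64.5% were still called. With the large libraries alone the ratios were 0.79 (0.64 and 0.94) and 0.94 (0.81 and 1.07), and 24.4% and 37% were still called, with fewer replicates. In the other 4 classes the term gave 0.85 to 0.93 at 2 days and 0.84 to 0.94 at 14 days, and the large libraries 0.73 to 0.87 and 0.75 to 0.91. The bound for this cause as a whole was under 0.5, written when counts of genes with the term, but not ratios, had been seen. A share of the library set in the changes was left open. Injury and library set were still partly joined, since the large set held 1 injured replicate at each of these times.

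Free RNA may stand behind tubular transcripts in endothelium at 12 hours. The fall of 9 proximal tubule transcripts in endothelium differed from that in all nuclei by a median of 1.78, and the median over 16 injury genes of the CPM in endothelium over that allowed by free RNA was 4.4 in the lowest of 3 replicates, with Havcr1 at 2.1 and Myc at 2.26 over the group. Both values passed the bound written beforehand against free RNA, but that bound took free RNA to have the profile of all nuclei, which was not measured, so neither excludes it. That reading was made after the values were seen. Tests without a profile, also added then, compared endothelium with stroma, which the same free RNA would reach. The fall differed by 0.44. The log2 ratio of endothelium to stroma over injury genes differed from that over proximal tubule transcripts by at most 0.34 in any replicate. Both are what free RNA of a shared source would give, as would like changes in both classes. These medians did not decide on single genes, such as Vcam1 at 313.8 CPM in endothelium and 37.65 in stroma. On the CPM scale of the gene tests, which differs, Vcam1 was at 339 and 42.4. Free RNA was left open for injury genes in stroma too.

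Splits of the samples were drawn for each count of genes. For the 25 comparisons of 3 with 3 replicates the real split was the only 1 of 10 with as many genes, and 10 splits are too few to exclude chance. Real counts ran from 9 to 3571, and the highest count of another split was 5, in proximal tubule at 6 weeks. For genes that differ among the 6 groups the real grouping was 1 of 100 in every class, which excludes chance at that level. The highest other counts were 217 in proximal tubule, 72 in thick ascending limb, 25 in distal convoluted and connecting tubule, 57 in endothelium and 74 in stroma.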

How the results depend on the processing

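The large libraries alone and library size class as a term were chosen after seeing the data, and all other alternatives were planned. No named gene, described list, share or difference of responses past its threshold turned direction under any alternative, and the reversals given here are of values that did not pass. Among all genes called, not only those named, a few turned with the large libraries alone. At 2 days direction was kept there by 99.8% in proximal tubule and 99.4% in thick ascending limb. Where no cause is named, the cause was not tested. Relative log expression factors and the replicate block kept all 25 counts of genes within 1.5 times. Of the 81 lists described 81 kept their side with the block, 80 with relative log expression factors, 80 with the large libraries, 72 with fry and 45 with an estimated correlation. Of named genes 497 of 512 kept their side in DESeq2, 514 of 518 with relative log expression factors and 430 of 518 with the large libraries, where 69 lost it. Leaving out replicates with under 50 nuclei removed nothing in the 5 classes tested for genes, where every replicate had more, and gave no value.

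DESeq2 called 1276 genes in proximal tubule at 14 days and 271 at 6 weeks, 111 in thick ascending limb at 6 weeks, 131 and 33 in distal convoluted and connecting tubule at 14 days and 6 weeks, 84 and 29 in endothelium at the same times and 90 in stroma at 6 weeks. With only the groups compared in the fit, 12-hour counts were 5725 in proximal tubule, 3668 in thick ascending limb, 2385 in distal convoluted and connecting tubule, 1702 in endothelium and 1279 in stroma. The 6-week counts were 9, 11 and 1 in proximal tubule, thick ascending limb and endothelium, the 14-day count in endothelium was 34, and Slc12a3 at 6 weeks turned to 0.03. With no filter on low counts, distal convoluted and connecting tubule had 114 and 28 genes at 14 days and 6 weeks, and endothelium 976, 1029, 200 and 121 from 12 hours to 6 weeks. Stroma had 103 at 6 weeks and 49 list tests past the threshold, genes that differ among groups numbered 2717 in endothelium and 2423 in stroma, and Emcn at 2 days in endothelium turned to -0.11.

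The large libraries alone, with fewer replicates, gave 541, 480 and 70 genes in proximal tubule and 426, 50 and 32 in thick ascending limb at 2 days, 14 days and 6 weeks. They gave 1974, 277 and 6 in distal convoluted and connecting tubule at 12 hours, 2 days and 14 days, 1228, 127, 11 and 19 in endothelium from 12 hours to 6 weeks, and 157 and 67 in stroma at 2 and 14 days. The lone injured replicate at 2 and 14 days was assumed to vary like the other groups. Reversed values were Umod 0.11 at 6 weeks, Slc12a3 0.19 and Calb1 0.46 at 14 days, Flt1 -0.40 at 2 days and 0.01 at 14 days, and in stroma Vcam1 0.20 at 2 days and 0.21 at 6 weeks and Pdgfrb -0.39 at 14 days. The share of proximal tubule at 2 days turned to 0.37, and 1 class changed in share at 12 hours and 1 at 2 days.

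With library size class as a term, counts at 2 and 14 days were 784 and 177 in thick ascending limb, 409 and 21 in distal convoluted and connecting tubule, 193 and 14 in endothelium and 210 and 146 in stroma. At 6 weeks Slc34a1 turned to 0.03, Slc5a12 to 0.08, Umod to 0.16 and Slc12a3 to 0.13, and at 14 days Calb1 to 0.35. The heat shock list in thick ascending limb at 4 hours turned direction at adjusted p = 0.906 in camera, and 1, 1, 2 and 1 classes changed in share from 12 hours to 6 weeks.

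The same number of nuclei in every replicate, and so fewer UMIs, gave 529 and 63 genes in proximal tubule at 14 days and 6 weeks and 663, 862, 826, 182 and 18 in thick ascending limb from 4 hours on. It gave 527, 639 and 424 in distal convoluted and connecting tubule at the 3 early times, 263, 110, 92 and 11 in endothelium at the first 4 and 231, 302, 96, 79 and 12 in stroma. Genes that differ among groups were then 1350, 895, 418 and 542 in the 4 classes other than proximal tubule. At 6 weeks Slc5a12 turned to 0.09, Slc12a3 to 0.04, Emcn to 0.01 and Lcn2 in endothelium to 0, and Pdgfrb at 14 days to -0.04. Without possible free RNA genes, and so with fewer genes, 14-day and 6-week counts were 436 and 54 in proximal tubule, 231 and 26 in thick ascending limb and 24 and 4 in endothelium. The heat shock list in thick ascending limb at 4 hours turned direction at adjusted p = 0.985 in camera, Slc12a3 at 6 weeks turned to 0.04 and Vcam1 in stroma at 6 weeks to 0.

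With the first library only, the count was 30 in thick ascending limb at 6 weeks, 384, 268, 19 and 4 in endothelium from 12 hours to 6 weeks, and 345 and 169 in stroma at 2 and 14 days. At 14 days in stroma Vcam1 turned to -0.08 and Pdgfrb to -0.03, and 1, 1 and 2 classes changed in share at 4 hours, 12 hours and 14 days. List tests past the threshold numbered 14, 14, 21, 12 and 5 with an estimated correlation, in the order proximal tubule, thick ascending limb, distal convoluted and connecting tubule, endothelium and stroma, and 31 in endothelium with fry. With the replicate number as a block Slc12a3 at 6 weeks turned to 0.01 and 1 class changed in share at 4 hours. Replicate numbers did not pair samples, since correlations of residuals within a number ran from -0.155 to 0.158 over 75 pairs. A prior count of 0.5 turned the immediate early difference at 2 days to -0.04.

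Shares with TMM over classes had 1 class changed at 4 hours, and the share of proximal tubule at 2 days turned to 0.03. Nuclei of at least the median UMIs gave 2, 2, 3 and 1 classes changed from 12 hours to 6 weeks, and the share of proximal tubule at 4 hours turned to -0.05. The share of immune at IRI4h turned to 4.58 there and passed, with median UMIs of immune nuclei of 456, 438 and 435.5 in sham and 444, 557 and 1102 at 4 hours. Without proximal tubule nuclei in the total 1 class changed at 12 hours and 2 at 14 days.

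Leaving out each replicate gave these lowest and highest counts of genes, in the order of time. Proximal tubule had 2235 to 3170, 2743 to 3788, 1164 to 3301, 465 to 1235 and 37 to 416, and thick ascending limb 706 to 1266, 1015 to 1910, 692 to 2810, 112 to 766 and 14 to 267. Distal convoluted and connecting tubule had 628 to 1134, 724 to 1360, 387 to 1798, 9 to 183 and 0 to 34, and endothelium 507 to 869, 285 to 777, 171 to 1309, 1 to 103 and 0 to 122. Stroma had 294 to 451, 516 to 932, 220 to 672, 142 to 333 and 13 to 108. At 2 days the highest count came without replicate 1 at 2 days in 4 of the 5 classes. At 14 days and 6 weeks it came without replicate 1 of that time in all 5. Genes that differ among groups in thick ascending limb ran from 1769 to 3491. Classes changed in share ran from 0 to 3, 0 to 4, 0 to 2, 0 to 3 and 0 to 2.

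Genes that failed their test and crossed 0 on leaving out a replicate ranged as follows. Slc5a12 at 2 days ran from -0.05 to 0.43, Umod at 6 weeks from -0.32 to 0.10, Slc12a1 at 6 weeks from -0.03 to 0.10, Calb1 at 14 days from -0.81 to 0.13 and Slc12a3 at 6 weeks from -0.14 to 0.21. In endothelium Flt1 at 4 hours ran from -0.33 to 0.17, and Emcn from -0.08 to 0.20 at 2 days and -0.28 to 0.04 at 6 weeks. In stroma Vcam1 ran from -0.49 to 0.22 at 2 days, -0.08 to 0.65 at 14 days and -0.32 to 0.41 at 6 weeks, and Pdgfrb at 14 days from -0.07 to 0.41. The heat shock list in thick ascending limb at 4 hours ran from adjusted p = 0.471 to 0.983 in camera.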

Other observations

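The fit of the large libraries alone was added after the data were seen, and the gene lists of this part were picked for description after that. In proximal tubule at 6 weeks the clock gene Npas2 rose from 9.82 ± 0.209 to 105 ± 90.7 CPM (3.43 ± 0.52, edgeR adjusted p = 0.0017) and Arntl, the core activator of the clock, from 28.4 ± 5.90 to 107 ± 21.9 CPM (1.91 ± 0.32, edgeR adjusted p = 0.0032), with n = 3 in each group. Their output gene Dbp was at 7.96 ± 1.64 CPM in sham and 1.48 ± 0.525 at 6 weeks (-2.32 ± 0.63, edgeR adjusted p = 0.099). Of 19 members of the clock list 2 rose, and 3 rose and 5 fell adjusted over the list alone. The list as a whole tested lower (camera adjusted p = 0.033, and adjusted p = 0.19 with an estimated correlation), against the direction of the 2 members past the gene test. That call was lost without sham 1 and without replicate 1 or 3 at 6 weeks. The hour of collection was not given in the sources used here.

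In endothelium at 12 hours Gbp3, a guanylate-binding protein of the interferon response, fell from 93.2 ± 33.3 to 22.0 ± 7.60 CPM (-2.13 ± 0.44, edgeR adjusted p = 0.0041), and the antiviral gene Rsad2 from 166 ± 54.8 to 58.7 ± 5.88 CPM (-1.51 ± 0.34, edgeR adjusted p = 0.0088), with n = 3 in each group. Gbp3 was at 5.53 CPM in immune nuclei. Ifi44 (-1.17 ± 0.40, edgeR adjusted p = 0.083) and Bst2 (-1.01 ± 0.39, edgeR adjusted p = 0.13) did not pass. Of 16 interferon genes 2 fell, and 3 adjusted over the list alone (camera adjusted p = 2.8e-05, and adjusted p = 0.22 with an estimated correlation). H2-K1 fell by 1.28 on the log2 scale, the 1 of 14 antigen presentation genes past the gene test, and 5 fell adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.22 with an estimated correlation). The calls were lost without replicate 1 at 12 hours for Gbp3, without sham 1 or replicate 2 at 12 hours for Rsad2, and without sham 1 or any replicate at 12 hours for H2-K1.

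Of 8 immune marker genes 2 rose in endothelium at 2 days, and 4 adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.37 with an estimated correlation). At 14 days 1 rose, and 3 adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.35 with an estimated correlation). S100a8, at 0 counts in sham, was at 24.4 ± 8.69 CPM at 2 days, at least 16.5-fold higher against 3 counts over the group, with 43.2 CPM in immune nuclei. Lyz2 rose from 6.17 ± 1.70 to 151 ± 92.0 CPM at 14 days (4.49 ± 0.80, edgeR adjusted p = 0.018), against 216 CPM in immune nuclei, a call lost without any 1 of the sham replicates, without replicate 3 at 14 days and with the large libraries alone, where the log2 change was 3.35.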
